A study of Mus musculus with 10 samples.

How the data were processed

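The deposited files were 10 tables of counts, 1 per library, with a cell in each line and a gene in each column, together with lists of cell barcodes. The values were whole-number UMI counts per cell and gene as the authors made them from 10x Genomics 3' libraries against the mouse genome build mm 10, per the labels' protocols, and the aligner and annotation were not stated. Barcodes with more than 20% mitochondrial counts were already absent from the deposited tables, as the values show. Each deposited table also held other values, a cluster number per cell given by the authors, which were not used in any comparison. Each library came from a pool of 3 male mice, and perfusion and dissociation used blockers of transcription and translation, per the labels. The barcode lists of CC025 replicate 2 and CC083 replicate 2 each matched the cells of the other library's count table; the group written in the name of the count table was used. An mCherry column was present only in knockdown replicate 1 and scramble replicate 1.

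Gene names were matched across the libraries, which gave 22885 names, 21960 of them matched to the mouse annotation and 16287 present in all 10 tables. Cells were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs, which all 184630 deposited cells met. Median UMIs per cell ran from 2432 in knockdown replicate 2a to 4619 in CC025 replicate 1. The precision at this depth is given as Poisson intervals for Homer1 and as the share of planted changes recovered. Doublets were scored with scrublet in scanpy 1.11.5, and in each library the highest-scoring cells were marked up to an expected rate of 0.8% per 1000 cells; 29615 cells were marked. All cells, the marked ones included, were scaled to 10000 UMIs, log-transformed and clustered without correction for batch (3000 variable genes, 40 principal components, 15 neighbours, Leiden resolution 1.0, seed 1), which gave 41 clusters. The marked cells were left out of every count, share and sum after the clusters were named. A cluster was named for the class whose markers, fixed before the data were examined, were most enriched, with at least 3 markers enriched 2-fold. A cluster stayed unnamed below this, where its median doublet score exceeded 0.3, where markers of another class stood beside those of the first, where cell-cycle genes led it or where it was shallow without markers. Of the clusters 30 were named into 16 classes and 11 were not (9 of these for their doublet score). Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

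Counts were summed per library over the cells of a class, where a library entered with at least 20 cells and a comparison needed at least 2 libraries in each group. Knockdown was compared with scramble and CC083 with CC025 by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, a filter on low counts and all 4 groups in the same fit. P values were adjusted by Benjamini-Hochberg over the genes of a class, and a call was an adjusted p below 0.05. CPM, fold changes and SDs were computed from these sums, with the SD taken over libraries. Gene lists, 28 in number, were tested with camera in limma 3.58.1 at a fixed correlation of 0.01, adjusted over all lists, classes and both comparisons, and beside it with a correlation estimated for each list. Where a count of list members is given as adjusted over the list alone, the Benjamini-Hochberg step used the members only. Cell class shares were compared by exact permutation of libraries. The thresholds, tests, lists and markers, and the rule for which genes are named, were fixed before the data were examined.

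The rule named Homer1 in every class. Among called genes with a mean of at least 10 CPM and the same sign in every same-numbered pair, it named the 6 highest and 6 lowest log2 fold changes in excitatory neurons and the 3 highest and 3 lowest in each other class, leaving out predicted genes. Where no gene of a class passed it named the 2 genes of smallest p in each direction, and in each list printed 2 to 4 members of smallest p. Genes named outside the rule are Mt3, Slc1a2, Snhg11, Ccl24, Ckm, Hist1h4d, Lars2, Pcsk1n, Ulk4, Retnla, AY036118 and Gm42418 where a small number of calls is listed; they were chosen after their values were seen.

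Alternatives were the replicate as a block, DESeq2 1.42.0, RLE size factors, no filter on low counts, only the 2 groups compared, each library left out in turn, marked doublets kept, at least 1000 UMIs, at most 10% mitochondrial UMIs, and libraries 2a and 2b summed. At least 0.5% mitochondrial UMIs, both 2a libraries left out, and a fit of neurons with at least 10 cells per library were added later. The fits of excitatory neurons, pericytes, smooth muscle and newly formed oligodendrocytes held 7 libraries with 3 residual degrees of freedom, and the block left fewer. Same-numbered libraries are paired because the labels give them the same batch, and for 2a and 2b the same day. As a check, deviations of paired libraries from their group means correlated at 0.56, 0.27 and 0.57 for the knockdown and scramble pairs and 0.50 for the line pairs in microglia, and at 0.35 and 0.15 and at 0.31 in astrocytes. In endothelial cells the knockdown and scramble pairs correlated at 0.39, 0.057 and 0.24, where the 2a pair lay below its highest correlation with a library of another number (0.072). The fits were tested on simulated data with the depths and spread of each class, in which 200 genes were changed by 2-fold or 4-fold; 34.3% and 97.0% of these were called in astrocytes between the lines and 21.5% and 84.0% in excitatory neurons. No libraries of the same group were alike enough to be the same sample measured again. Neurons of the knockdown and scramble libraries were left out of the planned comparison because too few libraries reached 20 cells.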

Results

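Single-cell RNA sequencing of mouse prefrontal cortex was deposited as 10 libraries, each made from a pool of 3 male mice. The libraries formed 4 groups: CC025 and CC083, which are inbred Collaborative Cross lines, with 2 libraries each, and C57BL/6J mice given in development a short hairpin RNA against Homer1a and Ania3 or a scrambled hairpin, with 3 libraries each. Homer1 encodes a postsynaptic scaffold protein, and Homer1a and Ania3 are its short isoforms. Same-numbered libraries came from the same batch, with 2a and 2b prepared on day 1 and day 2 of the same batch. The labels do not say whether 2a and 2b came from different mice; they were counted as separate libraries, so n = 3 would be 2 pools if they did not. CC025 replicates 1 and 2 held 65399315 and 90370414 UMIs (counted RNA molecules) in 13267 and 16756 cells, and CC083 replicates 1 and 2 held 73165950 and 114147097 UMIs in 19777 and 21120 cells. Knockdown replicates 1, 2a and 2b held 80461880, 20982259 and 117545975 UMIs in 24246, 7644 and 26256 cells, and scramble replicates 1, 2a and 2b held 62047851, 88479352 and 94191401 UMIs in 13765, 23053 and 18746 cells. Mitochondrial genes made up a median of 0.126% of the UMIs of a cell in scramble replicate 2a and 1.09% to 2.86% in the other libraries. The deposited tables held 184630 cells, all of which met the limits on UMIs, genes and mitochondrial RNA, and 29615 of them were marked as doublets and left out.

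Homer1 had its highest CPM in excitatory neurons in each library with at least 10 of them, but these held most of its UMIs only in the CC083 libraries (4717 of 5876 and 2706 of 4213). Its level there was 284 ± 16.1 CPM (mean and SD) in CC083 and 367 ± 138 CPM in CC025, a log2 fold change of -0.37 (SE 0.32, adjusted p 1.00, n = 2 each). Without CC025 replicate 2 the log2 fold change was 0.07. In the knockdown and scramble libraries only knockdown replicates 1 (58 cells) and 2b (23 cells) and scramble replicates 1 (271 cells) and 2b (11 cells) held at least 10 excitatory neurons. Without TMM scaling Homer1 lay at 135 CPM (95% CI 103 to 173, 60 UMIs) and 135 CPM (CI 69.7 to 236, 12 UMIs) in the knockdown neurons and at 212 CPM (CI 193 to 233, 436 UMIs) and 347 CPM (CI 220 to 520, 23 UMIs) in the scramble neurons. In an added fit with at least 10 neurons per library the log2 fold change of Homer1 was -0.88 (SE 0.42, p 0.0446, adjusted p 1.00, n = 2 each). In astrocytes Homer1 was 15.3 ± 0.619 CPM in knockdown (n = 3) and 24.7 ± 7.71 in scramble (n = 2), a log2 fold change of -0.79 (SE 0.34, p 0.032, adjusted p 0.568). Knockdown replicates 1, 2a and 2b held 29, 1 and 40 of its UMIs there, and scramble replicates 1 and 2b held 66 and 7. Without TMM scaling the 95% CI in knockdown replicate 2a was 0.421 to 92.7 CPM, so the small knockdown SD rests partly on 1 UMI. In microglia of the 2 lines Homer1 was 11.3 and 9.23 CPM in CC083 and CC025, a log2 fold change of 0.29 with adjusted p 0.483. In pericytes, the contractile cells of capillaries, Homer1 was 16.7 ± 6.43 CPM in CC083 and 5.71 ± 2.97 in CC025 (log2 fold change 1.56, SE 0.59, adjusted p 0.203). With the replicate as a block, which left fewer than the 3 residual degrees of freedom of that fit, the adjusted p was 0.0314. Markers of excitatory neurons moved the same way in pericytes (9 of 9 above 0, median log2 fold change 2.31). Over all cells, where the share of neurons enters the sum, Homer1 was 61.8 ± 24.7 against 24.0 ± 5.01 CPM in CC083 and CC025 (log2 fold change 1.36, SE 0.47, adjusted p 0.404). Over all cells of knockdown and scramble it was 8.87 ± 0.407 against 10.8 ± 5.74 CPM (log2 fold change -0.28, SE 0.38, adjusted p 1.00), and without scramble replicate 1 the log2 fold change was 0.23. By library this was 9.13, 8.41 and 9.09 CPM in knockdown replicates 1, 2a and 2b and 17.2, 6.28 and 8.83 CPM in scramble replicates 1, 2a and 2b. The gene counts joined all 12 annotated Homer1 transcripts, so the short isoforms that the hairpin targets were not measured apart, and these values do not check the knockdown.

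In the other classes Homer1 did not pass either. Between knockdown and scramble its log2 fold change was -0.97 (SE 0.47) in newly formed oligodendrocytes, 0.56 (SE 0.34) in endothelial cells, 0.59 (SE 0.60) in border macrophages, -0.14 (SE 0.33) in oligodendrocytes, 0.11 (SE 0.34) in oligodendrocyte precursors and -0.03 (SE 0.17) in microglia, each with adjusted p 1.00. Several of these turned with a library left out: border macrophages to -0.03 and oligodendrocyte precursors to -0.04 without knockdown replicate 1, oligodendrocytes to 0.28 without scramble replicate 1, and oligodendrocyte precursors to -0.03 without scramble replicate 2a. Homer1 in microglia turned to 0.01, 0.03 and 0.04 without knockdown replicate 1, knockdown replicate 2b and scramble replicate 1. Between CC083 and CC025 it was 0.53 (SE 0.46) in smooth muscle, 0.49 (SE 0.35) in endothelial cells, 0.46 (SE 0.67) in border macrophages, 0.36 (SE 0.26) in astrocytes, 0.35 (SE 0.28) in oligodendrocytes and 0.01 (SE 0.31) in oligodendrocyte precursors, with adjusted p from 0.614 to 1.00. In the precursors it turned to -0.12 without CC025 replicate 1 and to -0.12 without CC083 replicate 1.

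**Figure D1:**
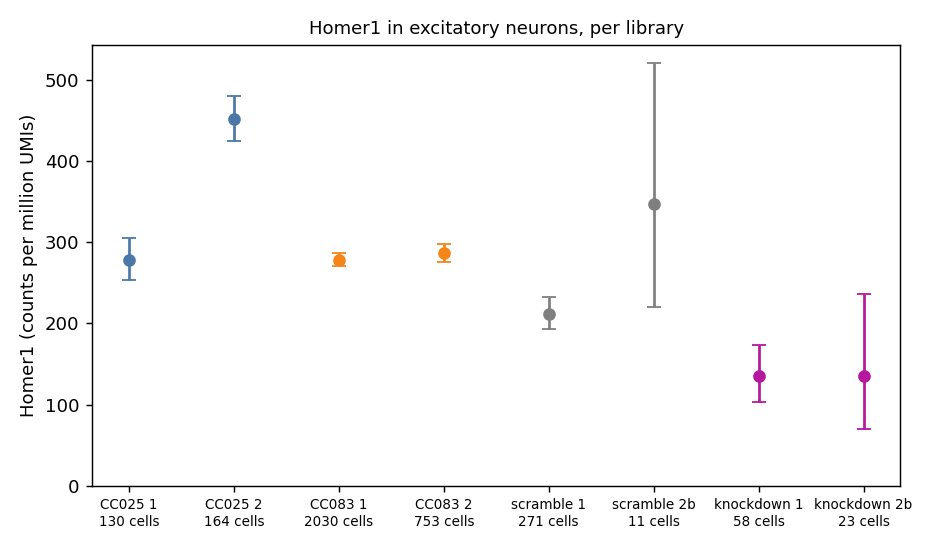
Homer1 CPM in excitatory neurons of each library with at least 10 of them, with its 95% Poisson interval and the number of cells.

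Microglia, the resident macrophages of the brain, were the largest class in 8 of the 10 libraries and made up 68.6% ± 16.1 (mean and SD over libraries) of retained knockdown cells (n = 3), 69.5% ± 28.5 of scramble cells (n = 3), 24.9% ± 0.277 of CC083 cells and 35.8% ± 3.24 of CC025 cells (n = 2 each). Excitatory neurons made up 8.24% ± 5.59 of CC083 cells against 1.11% ± 0.024 of CC025 cells (7.40-fold, a difference of 7.13 percentage points), at 12.2% against 1.10% in batch 1 and 4.29% against 1.13% in batch 2. Inhibitory neurons made up 1.02% ± 0.749 of CC083 cells against 0.143% ± 0.085 of CC025 cells, and border macrophages, which lie in the brain's coverings and around its vessels, 0.557% ± 0.393 against 1.67% ± 0.519. Endothelial cells made up 9.59% ± 0.288 against 10.9% ± 1.14. In knockdown cells excitatory neurons made up 0.141% ± 0.144 against 0.768% ± 1.25 in scramble cells, and without scramble replicate 1 the difference turned from -0.627 to 0.095 percentage points. Endothelial cells made up 5.19% ± 4.74 of knockdown cells against 9.52% ± 5.41 of scramble cells, lower in all 3 pairs. A share of cells depends on the dissociation, so these values do not give the composition of the tissue. No share passed: every adjusted p was 1.00 over 32 exact permutation tests, in which the lowest p attainable was 0.333 between the lines and 0.1 between knockdown and scramble. The cells formed 41 clusters, of which 30 were named into 16 classes, and 4096 of the 155015 retained cells lay in unnamed clusters. Microglia of CC025 made up 4450 and 4711 of the 9358 retained cells of 1 cluster, and those of CC083 4088 and 4210 of the 8434 of another. Astrocyte clusters also parted the lines, and endothelial clusters parted the lines from the other mice. Microglial clusters also parted the knockdown and scramble libraries: a cluster with a median of 0.123% mitochondrial UMIs held 13441 of 16889 microglia of scramble replicate 2a and 4352 of 9812 of knockdown replicate 1, and another held 5063 of 5755 of knockdown replicate 2a. Therefore classes rather than clusters were compared.

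**Figure D2:**
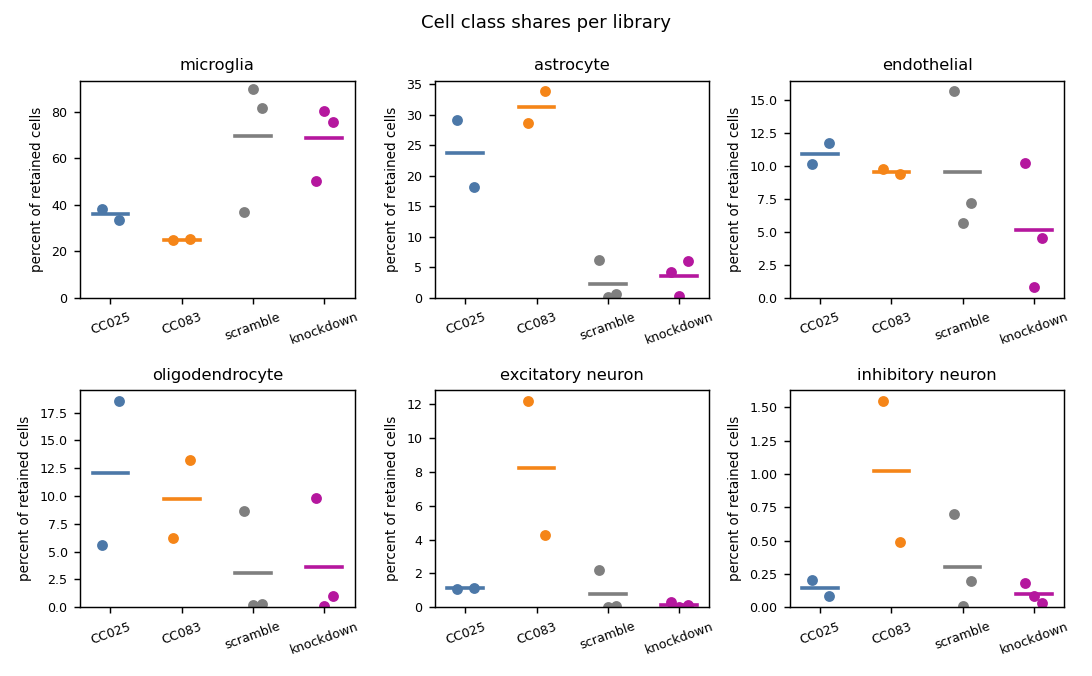
Percent of retained cells in 6 classes, with a point for each library and a bar for the mean of its group.

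No gene passed between knockdown and scramble in any of the 9 classes with enough cells. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, had one of the lowest p values in 5 of the classes and was lower in knockdown in each. It was 118 ± 83.6 against 544 ± 254 CPM in astrocytes (n = 3 and 2, log2 fold change -1.98, SE 0.39, adjusted p 0.568), 47.0 against 184 CPM in newly formed oligodendrocytes and 73.3 against 199 CPM in oligodendrocyte precursors. S100b, a calcium-binding glial protein gene, was 11.5 ± 4.85 against 3.68 ± 0.871 CPM in microglia (log2 fold change 1.65, SE 0.32, adjusted p 1.00, n = 3 each). In fibroblasts the interferon-induced Gbp2 had a log2 fold change of 2.81 (124 against 17.3 CPM) and Iigp1 of 3.69, and the Notch target Hes1 one of -1.79 (60.3 against 208 CPM). Each had an adjusted p of 0.0916 (n = 2 and 3). Sgk1, a glucocorticoid-induced kinase gene, was 417 ± 430 against 138 ± 53.4 CPM in oligodendrocytes, and Dusp8 32.1 against 14.1 CPM in endothelial cells. The counts at unadjusted p < 0.05 by edgeR were 1002 in astrocytes, 333 in microglia, 183 in endothelial cells, 157 in border macrophages, 128 in oligodendrocyte precursors, 118 in newly formed oligodendrocytes, 109 in fibroblasts, 95 in oligodendrocytes and 74 in monocytes or neutrophils (2199 in all). In oligodendrocyte precursors AY036118 and Gm42418 fell together with Lars2, at -1.42, -1.54 and -1.28 with no filter on low counts and at -1.70, -1.67 and -1.51 without both 2a libraries and with the block. With the block AY036118 was also called lower in oligodendrocytes (-1.89, adjusted p 0.00279). What moved these genes together was not tested, so the fall of Lars2 cannot be read as a change of that gene alone. DESeq2 called 2, S100b and Zbtb26, both in microglia. Whether RNA of other glial classes entered the microglial sums was not tested, so S100b was not shown to change within microglia. With the replicate as a block 28 passed (13 higher, 15 lower), among them Lars2 in newly formed oligodendrocytes (adjusted p 1.3e-04), oligodendrocytes (2.3e-06) and oligodendrocyte precursors (0.034), Cldn5, Sgk1 and Dusp8. Lars2 in astrocytes was the 1 call without knockdown replicate 2b and the 1 call in fits of the 2 groups alone. Mt3 and Slc1a2 in endothelial cells were the 2 calls without scramble replicate 1, and with no filter on low counts there were 106. Slc1a2 is among the fixed astrocyte markers, and whether RNA of astrocytes entered the endothelial sums was not tested. In simulated counts with the depth and spread of each class, 42.1% of 2-fold and 72.4% of 4-fold changes were called in microglia, 31.6% and 77.6% in endothelial cells, 30.9% and 88.0% in oligodendrocyte precursors and 17.3% and 86.6% in astrocytes. Unchanged genes made up 5 of 116, 12 of 119, 14 of 132 and 10 of 111 of the simulated calls in these classes, in that order.

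Ribosomal protein genes and genes of oxidative phosphorylation, which encode the nuclear part of the respiratory chain, were higher in knockdown astrocytes. The median log2 fold change was 0.46 for the ribosomal list (80 of 81 members above 0, adjusted p 5.8e-19, among them Rpl37 at 0.91 and Rpl6 at 0.73) and 0.58 for the oxidative phosphorylation list (79 of 82, adjusted p 4.3e-23, among them Ndufb11 at 0.97 and Ndufa7 at 0.96), and with an estimated correlation the adjusted p was 0.779 for both. RNA quality of these astrocytes differed in the later pair: those of knockdown replicate 2b had a median of 1518.5 UMIs against 3255 in scramble replicate 2b. An astrocyte cluster with a median of 1208 UMIs and 8.16% mitochondrial UMIs held 669 and 8 of their 1266 and 101 retained cells. Without knockdown replicate 2b the adjusted p was 9.5e-09 and 2.5e-15. Both were also higher in knockdown microglia, at 0.32 for ribosomal genes (adjusted p 5.3e-06, with estimated correlation 0.788), a call lost without knockdown replicate 2a (adjusted p 0.407), and at 0.22 for oxidative phosphorylation (8.3e-05, with estimated correlation 0.788), lost without knockdown replicate 2a (0.285) or scramble replicate 1 (0.0549). Mitochondrially encoded genes were higher in knockdown microglia (0.64, 13 of 13, adjusted p 2.6e-04, with estimated correlation 0.788; mt-Co1 3582 ± 2127 against 1931 ± 1322 CPM), and without scramble replicate 2a, the library with least mitochondrial RNA, the median was 0.16 with adjusted p 0.999. Without knockdown replicate 2a it was 0.21 with adjusted p 0.0386. The same genes were higher in endothelial cells (0.60, adjusted p 7.6e-07), border macrophages (0.36, 4.8e-04), oligodendrocyte precursors (0.30, 2.4e-07) and fibroblasts (0.21, 0.0084), with estimated correlation 0.779, 0.788, 0.779 and 0.788. In fibroblasts the block ended the call and turned the median to -0.23 (2 of 13 above 0, adjusted p 0.115). Without scramble replicate 2a none of these 4 passed as higher, border macrophages (-0.19, 0.0304) and oligodendrocyte precursors (-0.15, 0.0326) passed as lower, and border macrophages also lost the call without knockdown replicate 2a (0.0903). With 2a and 2b summed the median was -0.49 in precursors, -0.09 in border macrophages, -0.01 in endothelial cells and 0.17 in microglia. With only cells of at least 0.5% mitochondrial UMIs it was -0.19 in fibroblasts, 0.24 in border macrophages, 0.53 in endothelial cells and 0.51 in microglia. The genes were lower in newly formed oligodendrocytes (-0.68, 0 of 13 above 0, adjusted p 1.4e-07, with estimated correlation 0.779), where the 2a libraries had too few cells to enter. Without both 2a libraries they passed as lower in 7 of the 9 classes, from -0.27 in microglia to -0.61 in oligodendrocyte precursors and -0.68 in newly formed oligodendrocytes. They did not pass in astrocytes (-0.07, adjusted p 0.632) and fibroblasts (-0.21, 0.0865), and an estimated correlation was not run with libraries left out. Myelin genes were higher in knockdown endothelial cells (0.99, 13 of 14, adjusted p 8.8e-09, with estimated correlation 0.779; Mbp 150 against 74.4 CPM). They were also higher in microglia (0.61, 14 of 14, adjusted p 1.1e-04, with estimated correlation 0.782), a call lost without knockdown replicate 1 (0.238). Myelin genes belong to oligodendrocytes, and whether RNA of those cells entered the sums of other classes was not tested here. Oligodendrocytes made up 9.81%, 0.111% and 1.05% of the cells of knockdown replicates 1, 2a and 2b. In scramble replicates 1, 2a and 2b they made up 8.67%, 0.186% and 0.276%. In these ribosomal, oxidative phosphorylation, mitochondrially encoded and myelin lists 0 members were called and 0 passed when adjusted over the list alone. Interferon-response genes were higher in knockdown fibroblasts (1.21, 12 of 15, adjusted p 1.2e-06, with estimated correlation 0.779), where 5 members passed when adjusted over the list alone, among them Gbp2, Ifit3, Ifit1 and Isg15. Cell-cycle genes were lower in knockdown oligodendrocyte precursors (-0.62, 1 of 12 above 0, adjusted p 1.1e-05, with estimated correlation 0.779), with Mcm3 at 17.9 against 43.5 CPM, and 2 members passed when adjusted over the list alone. A precursor-like cluster led by cell-cycle genes had stayed unnamed, so its cells (6, 32 and 28 retained in knockdown replicates 1, 2a and 2b and 5, 12 and 25 in scramble) were not in this class. In all 55 of 213 list tests passed between knockdown and scramble (39 higher, 16 lower) at the fixed correlation. These became 22 higher and 20 lower without scramble replicate 2a and 23 and 25 without both 2a libraries. With all libraries none passed with an estimated correlation, and no member of the lists named here was itself called. The fixed correlation treats the genes of a list as nearly independent.

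Neurons of the knockdown and scramble libraries were too few for the planned comparison, and the fit below was added after the cell numbers were seen. Among 11707 genes in excitatory neurons edgeR called 0 (450 at unadjusted p < 0.05), and with the replicate as a block it called 38 (33 higher, 5 lower), where Homer1 had a log2 fold change of -0.82 and adjusted p 0.635. Microglial genes were higher in the knockdown neurons, both the homeostatic list (median 1.17, adjusted p 2.5e-10, with estimated correlation 0.799) and the activated list (1.31, adjusted p 1.8e-08, with estimated correlation 0.799). With excitatory and inhibitory neurons summed the medians were 0.24 (adjusted p 0.0137, with estimated correlation 0.969) and 0.24 (0.111). Microglia made up 50.2% and 75.5% of the cells of knockdown replicates 1 and 2b and 36.8% and 81.7% of those of scramble replicates 1 and 2b. Whether their RNA entered the neuron sums was not tested, so these lists do not show a change within neurons. GABA-A receptor genes, which encode the subunits of the main inhibitory receptor, had a median of -0.28 with adjusted p 0.0816. In the summed neurons it was -0.31 (0.111), and with the block -0.33 (0.0152, with estimated correlation 0.9496). In the summed neurons Homer1 had a log2 fold change of -0.64 (SE 0.42, p 0.158). Only 11 scramble and 23 knockdown neurons stood for the later batch.

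CC083 and CC025 differed in 3327 gene-by-class calls over 11 classes (1783 higher in CC083, 1544 lower). Both lines were counted against the same reference genome, so a value near 0 in 1 line was not separated from reads lost at its variants. In simulated counts unchanged genes made up 21 of 151 calls in astrocytes and 16 of 115 in excitatory neurons. They made up 14 of 133 in oligodendrocytes and 3 of 83 in microglia. Excitatory neurons held 43 of the calls (13 higher, 30 lower, of 12533 genes). Hjurp, which encodes a centromere histone chaperone, was 98.7 ± 9.02 against 11.5 ± 0.668 CPM in these neurons (8.59-fold, SE of log2 0.30, adjusted p 2.2e-04), Tpm3-rs7 89.0 ± 9.44 against 14.6 ± 8.57 (5.96-fold, adjusted p 0.00238) and the zinc-finger gene Zfp605 27.2 ± 7.25 against 0. Crym, a thyroid-hormone-binding protein gene of neuron subtypes, was 89.4 ± 14.6 against 21.8 ± 9.44 CPM (log2 fold change 2.05, SE 0.39, adjusted p 0.0333). That call was lost without CC025 replicate 2 (adjusted p 0.118), in fits of the 2 groups alone (0.0583), with at least 1000 UMIs (0.0573), with at least 0.5% mitochondrial RNA (0.0971) and with doublets kept (0.0993). CTGF was 22.9 ± 8.83 against 1.83 ± 0.638 CPM (log2 fold change 3.65, adjusted p 0.0162; 0.0927 with doublets kept). Lower in CC083 were Echdc2 (log2 fold change -4.71, SE 0.60, adjusted p 0.00181), the iodide transporter gene Slc5a5 (2.19 against 21.5 CPM, -3.34, SE 0.42, adjusted p 0.00168) and Il11ra1, a cytokine receptor gene (3.02 against 28.9 CPM, -3.31, SE 0.41, adjusted p 0.00168). The 43 calls became 448 with the replicate as a block, 207 with no filter on low counts, 124 without CC083 replicate 2, 20 with at least 1000 UMIs and 21 in fits of the 2 groups alone. The total became 7984 with the block, 6092 with no filter, 1610 without CC025 replicate 2, 1996 without CC083 replicate 1 and 2131 without CC025 replicate 1.

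**Figure D3:**
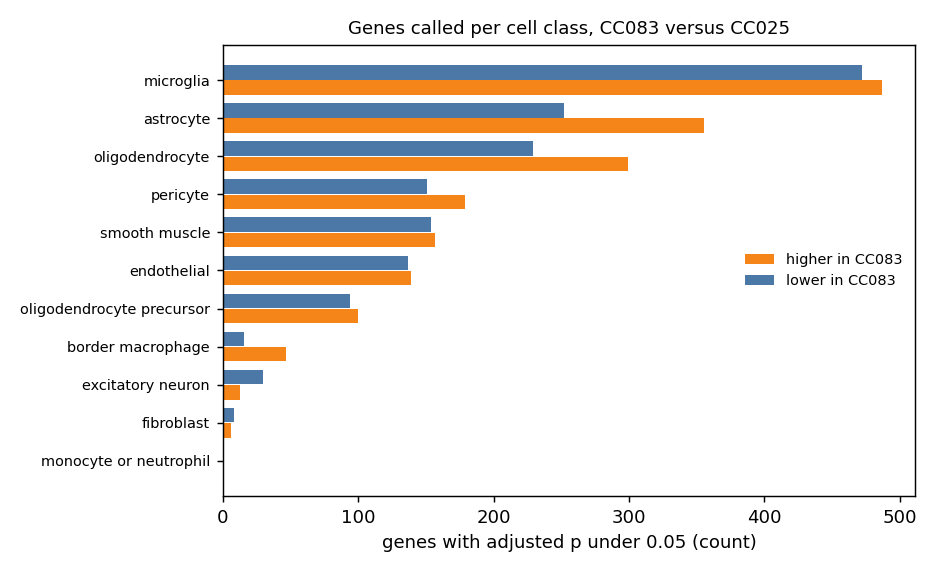
Genes called higher and lower in CC083 than in CC025 in each class with enough cells.

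In excitatory neurons of CC083 the GABA-A receptor genes had a median log2 fold change of 0.32 (8 of 12 above 0, adjusted p 0.033, with estimated correlation 0.779), with Gabrg1 at 1.35, Gabrb2 at 0.59 and Gabrd at 0.49. No member was called, by itself or when adjusted over the list alone (0 and 0). The call was lost without CC025 replicate 1 (adjusted p 0.058), CC025 replicate 2 (0.123) or CC083 replicate 1 (0.201). Immediate early genes, which neurons switch on when active, were lower in CC083 (median -0.43, 3 of 22 above 0, adjusted p 0.016, with estimated correlation 0.813), with Fosb at -1.05. Of the members 0 were called and 1 passed when adjusted over the list alone. That list turned higher without CC083 replicate 1 (adjusted p 0.974) and without CC025 replicate 2 (0.0939). Immediate early genes were also lower in CC083 pericytes, which are not neurons. Whether handling of the tissue moved them was not tested, so these values do not show lower neuronal activity. Homer binding partners, the genes whose proteins the scaffold ties together, had a median of -0.12 and did not pass (adjusted p 0.31). Reactive astrocyte genes were lower in the CC083 neurons (-1.26, 1 of 8 above 0, adjusted p 3.2e-04, with estimated correlation 0.779), with Serpina3n at 25.4 against 63.2 CPM, 0 called and 2 passing when adjusted over the list alone. The same list was lower in CC083 astrocytes. Whether RNA of astrocytes entered the neuron sums was not tested, so a change within neurons was not shown. Over the 11 classes 119 of 270 list tests passed between the lines at the fixed correlation (63 higher, 56 lower), and none passed with an estimated correlation.

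Microglia held the most calls between the lines, 959 (487 higher in CC083, 472 lower). Hspb3, a small heat-shock protein gene, was 46.8 against 0.0216 CPM and Myo18b, a muscle myosin gene, 30.3 against 0.0655 CPM in CC083 and CC025, while Glrp1 was 0.0227 against 47.5 CPM. Rspo1, a Wnt-pathway ligand gene, was 0.747 against 58.5 CPM (log2 fold change -6.30, SE 0.37, adjusted p 1.1e-05, n = 2 each). Interferon-response genes were lower in CC083 (median -1.11, 3 of 22 above 0, adjusted p 7.6e-07, with estimated correlation 0.779), with Gbp3 at 5.19 against 22.2 CPM, Ifit2 at 5.46 against 47.6 and Xaf1 at 18.9 against 78.6. Of the members 6 were called and 8 passed when adjusted over the list alone. Cholesterol-synthesis genes were higher (median 0.55, 18 of 19 above 0, adjusted p 5.0e-05, with estimated correlation 0.779), with Cyp51 at 31.7 against 14.5 CPM, Lss and Idi1. Of the members 5 were called and 6 passed when adjusted over the list alone. Genes of the list of heat shock and dissociation stress (heat-shock genes below) were lower (median -0.63, 0 of 14 above 0, adjusted p 4.0e-04, with estimated correlation 0.779), with Dnajb1 at -0.73 and Hsph1 at -0.76. Of the members 3 were called and 5 passed over the list alone. Ribosomal protein genes were lower (-0.59, 2 of 82 above 0, adjusted p 1.6e-08, with estimated correlation 0.788), with 0 called and 0 passing over the list alone, and the list call was lost without CC083 replicate 1 (0.276). The 959 calls became 1621 with the replicate as a block, 1529 by DESeq2, 418 without CC025 replicate 1, 457 without CC025 replicate 2 and 534 without CC083 replicate 1. The line difference is also a difference of cluster here, since microglia of each line formed a cluster of their own.

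Astrocytes held 607 calls between the lines (355 higher in CC083, 252 lower). Prss56, a trypsin-like serine protease gene, was 710 ± 85.3 against 1.08 ± 0.935 CPM (log2 fold change 9.21, SE 0.48, adjusted p 5.2e-10, n = 2 each), and Cideb, a lipid-droplet gene, 32.2 ± 17.1 against 0.724 CPM. Lower in CC083 were Tes (0.909 against 49.1 CPM), the innate immune receptor gene Tlr1 (0.265 against 20.8) and Bdh2 (2.04 against 42.9). Cholesterol-synthesis genes were lower in CC083 astrocytes, the opposite of microglia (median -0.25, 4 of 19 above 0, adjusted p 0.0021, with estimated correlation 0.779). Pmvk, which encodes a kinase of the pathway, was called at 88.6 against 167 CPM and also passed when adjusted over the list alone. Reactive astrocyte genes were lower (-0.88, 1 of 8 above 0, adjusted p 0.0074, with estimated correlation 0.779), a call lost without CC083 replicate 2 (0.0544). Gfap, the intermediate filament gene of reactive astrocytes, was the 1 member called, at 8.90 ± 4.29 against 33.0 ± 1.83 CPM (adjusted p 0.0231), and 3 passed when adjusted over the list alone. The 607 calls became 1219 with the replicate as a block, 1206 with no filter on low counts, 190 by DESeq2, 300 without CC083 replicate 1, 380 without CC025 replicate 2 and 399 without CC025 replicate 1.

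Oligodendrocytes held 528 calls between the lines (299 higher in CC083, 229 lower) and their precursors 194 (100 higher, 94 lower). Abca8a, a lipid transporter gene, was 149.5 against 0.334 CPM in oligodendrocytes (log2 fold change 8.58, adjusted p 5.7e-10), while Serpinb1a was 0.110 against 225 CPM and the proteoglycan gene Spock1 4.65 ± 1.20 against 266 ± 59.2 (log2 fold change -5.90, SE 0.30, adjusted p 1.5e-08). Itih5, whose protein binds the matrix component hyaluronan, was 1993 ± 261 against 9.66 ± 3.59 CPM in precursors (log2 fold change 7.73, SE 0.50, adjusted p 2.1e-08), and Stambpl1 62.5 against 1.93 CPM. Dmrtb1 was 0 against 30.8 CPM in precursors and the histone gene Hist1h4d 5.04 against 132. Heat-shock genes were lower in CC083 oligodendrocytes (median -0.71, 1 of 14 above 0, adjusted p 7.6e-07, with estimated correlation 0.779), with Hspa1a at -3.34 and Hspa1b at -3.45. Of the members 4 were called and 5 passed when adjusted over the list alone. The 528 calls became 1414 with the replicate as a block, 1022 with no filter, 299 by DESeq2, 300 in fits of the 2 groups alone and 236 without CC025 replicate 2. The 194 became 411 with the block, 335 with no filter, 121 by DESeq2, 86 without CC025 replicate 1, 107 without CC025 replicate 2 and 108 without CC083 replicate 1.

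Vascular classes differed between the lines in 276 endothelial, 330 pericyte and 311 smooth muscle calls. In endothelial cells the class I antigen-presentation gene H2-Q7 was 34.1 against 0.187 CPM and Vil1, an actin-bundling protein gene, 24.6 against 0.723, while the desmosome gene Dsp was 0.122 against 32.7. The checks of shared 3' ends and of lost reads given below covered genes called in 5 or more classes. Neither H2-Q7 nor H2-Q4 was among them, so lower expression of these in CC025 was not told apart from lost reads. Genes of MHC class I were higher in CC083 endothelial cells (median 0.62, 11 of 13 above 0, adjusted p 0.0017, with estimated correlation 0.782), with 4 called and 6 passing when adjusted over the list alone, and the list call was lost without CC083 replicate 2 (0.865). Heat-shock genes were lower in the same cells (-0.78, 1 of 14 above 0, adjusted p 1.6e-07, with estimated correlation 0.779), with Hspb1, the 1 member called, at 512 against 1903 CPM and 8 passing over the list alone. In pericytes the collagen receptor gene Mrc2 was 81.0 against 2.61 CPM (log2 fold change 4.90), Kcnmb1, a potassium channel subunit gene, 1.22 against 53.8 (-5.37) and Msc 0.885 against 76.5 (-6.26). Oxidative phosphorylation genes were lower in CC083 pericytes (-0.63, 1 of 81 above 0, adjusted p 5.8e-19, with estimated correlation 0.779), with Ndufa4 at -1.24 and Cox7a1 at -2.08. Of the members 3 were called and 3 passed over the list alone. Immediate early genes were also lower there (-1.23, 2 of 16 above 0, adjusted p 2.2e-04, with estimated correlation 0.788), with Jun at 52.8 against 235 CPM, 6 called and 6 passing over the list alone, and the list call was lost without CC025 replicate 2 (0.826). In smooth muscle H2-Q4 was 25.0 against 0.478 CPM and Optc, a proteoglycan gene, 0.327 against 21.8. Endothelial calls became 1118 with the block, 866 with no filter, 120 to 175 without CC025 replicate 2, CC025 replicate 1 or CC083 replicate 1, in rising order. Pericyte calls became 920 with the block, 527 with no filter, 71 by DESeq2, 162 with the 2 groups alone, 174 without CC025 replicate 2 and 832 without CC083 replicate 2, and smooth muscle calls 620 with the block, 64 by DESeq2, 40 without CC025 replicate 2 and 191 without CC083 replicate 1.

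Border macrophages differed between the lines in 63 calls (47 higher in CC083, 16 lower). The gelatinase gene Mmp9 was 61.9 against 0 CPM (adjusted p 0.00345, and 0.0799 without CC025 replicate 2). Interferon-response genes were lower in CC083 border macrophages (median -1.56, 2 of 21 above 0, adjusted p 5.8e-05, with estimated correlation 0.779), as in microglia, with Oasl2 at -3.90, Bst2 at -1.56 and Ifi27l2a at -1.52. Of the members 0 were called and 6 passed when adjusted over the list alone. In monocytes or neutrophils the 2 calls were H2-Eb1, a class II antigen-presentation gene (6919 ± 2246 against 244 ± 30.3 CPM, log2 fold change 4.83, SE 0.43, adjusted p 0.00112; 0.0636 without CC025 replicate 2), and 9930111J21Rik2 (1.86 against 258 CPM). Fibroblasts held 14 calls (6 higher, 8 lower), among them the paraoxonase gene Pon2 (140 against 8.02 CPM, log2 fold change 4.26) and the protease inhibitor gene Serpind1 (1.56 against 110 CPM). Pon2 was lost without CC025 replicate 2 (adjusted p 0.102) or CC083 replicate 2 (0.0743) and Serpind1 without CC083 replicate 2 (0.130). The 63 border macrophage calls became 249 with no filter, 116 with the 2 groups alone, 35 without CC025 replicate 1, 20 without CC025 replicate 2, 19 without CC083 replicate 1 and 37 without CC083 replicate 2. Fibroblast calls became 56 with the block, 187 with no filter, 30 by DESeq2, 7 with the 2 groups alone and 1, Snhg11, without CC083 replicate 2. Monocyte calls became 67 with the block, 159 with no filter, 14 by DESeq2, 5 with doublets kept (also Ccl24, Ckm and Hist1h4d), 10 without CC025 replicate 1 and 1 without CC025 replicate 2.

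Among 2222 genes called between the lines in any class, 607 were called in 2 or more and 546 of these in the same direction each time. The predicted interferon-inducible GTPase gene 9930111J21Rik2 was lower in CC083 in 10 of the 11 classes (median log2 fold change -6.81) and Hjurp higher in 10 (3.03). In 5 or more classes 70 genes were called, 69 of them in a single direction. The chance of a call differed with class size, so a gene absent from a class list was not shown to be equal there.

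Synaptic-vesicle genes, which belong to neurons, were higher in CC083 in glial classes. In astrocytes the median was 0.85 (19 of 21 above 0, adjusted p 7.3e-10, with estimated correlation 0.779), with Slc17a7, the vesicular glutamate transporter gene, at 29.7 against 4.98 CPM, 10 members called and 12 passing when adjusted over the list alone. In oligodendrocytes it was 0.86 (19 of 22, adjusted p 2.9e-07, with estimated correlation 0.779), with Cplx1 at 3.18, 8 called and 12 passing over the list alone, and in microglia 2.22 (19 of 23, adjusted p 1.7e-06, with estimated correlation 0.779), with Syp at 2.51, 3 called and 4 passing over the list alone. Markers of excitatory neurons made up 301 and 109 CPM of the UMIs of CC083 microglia and 43.7 and 42.2 CPM of those of CC025 microglia, in libraries where excitatory neurons made up 12.2%, 4.29%, 1.10% and 1.13% of cells. In the other libraries marker level and share did not always go together: it was 74.9 CPM at 0.0139% in knockdown replicate 2a and 46.3 CPM at 2.21% in scramble replicate 1.

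**Figure D4:**
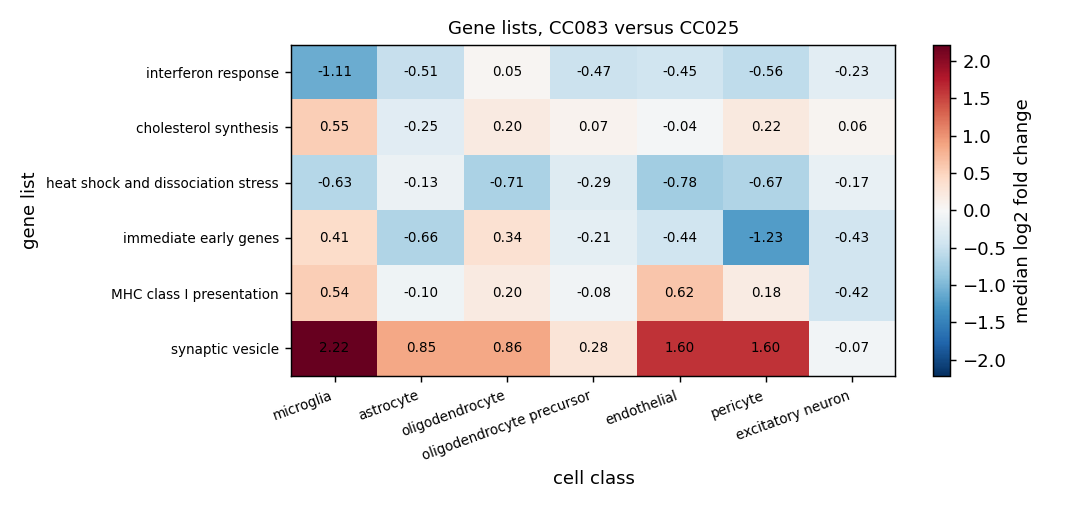
Median log2 fold change of 6 gene lists in 7 classes, CC083 against CC025.

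Fold changes of knockdown against scramble and of CC083 against CC025 were weakly related across genes: the Pearson correlation was 0.16 in microglia, 0.10 in endothelial cells, 0.00 in border macrophages, -0.01 in fibroblasts, -0.06 in oligodendrocytes and -0.16 in astrocytes. With a library left out it ran from 0.014 (without scramble replicate 2a) to 0.266 (without scramble replicate 1) in microglia. It ran from 0.025 (without knockdown replicate 2b) to 0.180 (without scramble replicate 1) in endothelial cells and from -0.233 (without CC025 replicate 2) to -0.076 (without CC025 replicate 1) in astrocytes. In oligodendrocytes it turned to 0.110 without scramble replicate 1, and in border macrophages and fibroblasts it took both signs. No gene was shared among the calls, because knockdown and scramble had none. With the replicate as a block Pcsk1n and Ulk4 were called higher in both in endothelial cells (2 genes, 0.403 expected by chance) and Retnla in monocytes or neutrophils (1 gene, 0.00251 expected). The other 7 genes called in both with the block went in opposite directions, 4 in endothelial cells, 2 in oligodendrocytes and 1 in fibroblasts. An expected number was not computed for opposite directions. More of the shared genes went in opposite directions than in the same, so the overlap does not show that the comparisons moved alike.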

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

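The tests of free RNA in non-neuronal classes, of strain variants, of mitochondrial RNA in 1 scramble library and of regrouped libraries were chosen after seeing results, while those of doublets, paralogs and free RNA in many classes were written before. Cholesterol-synthesis genes differed between CC083 and CC025 in opposite ways in microglia and astrocytes, which brought them here as an effect that differs between groups. The line difference of microglia minus that of astrocytes, tested as an interaction over 9 libraries, had a median log2 of 0.84 over 19 members (adjusted p 2.1e-19, with estimated correlation 0.0338). With the replicate as a block the adjusted p was 5.1e-11, with estimated correlation 0.501. By single genes the line difference of microglia and astrocytes differed for 4 of 11483 (463 at unadjusted p < 0.05), and with the block for 18. These were Ldhb, higher in microglia, and Kyat3, Abcd2 and Slc1a3, lower, all named after their values were seen. In 61 genes CC083 was called higher in 1 class and lower in another, with the same sign in every pair. For these the difference itself was tested only between microglia and astrocytes. S100a10, Trim47 and Ralgps2, called in opposite ways there, passed with the block (adjusted p 0.0358, 0.0319 and 0.0470) and not without it, and were also named after their values were seen. Itih5 was higher in astrocytes and oligodendrocyte precursors and lower in endothelial cells, a difference that was not tested.

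The reporter mCherry, a column that no comparison used, was read in inhibitory neurons of the only 2 libraries that carried it. It was present in 65.7% of inhibitory neurons in knockdown replicate 1 (23 of 35, CI 47.8 to 80.9, 1136 CPM, median 5211 UMIs per cell) and in 89.5% in scramble replicate 1 (77 of 86, CI 81.1 to 95.1, 2051 CPM, median 4726.5 UMIs). In microglia, taken as a class without the reporter, 0.102% and 0.155% of cells held an mCherry UMI at medians of 2291 and 3416.5 UMIs. In excitatory neurons 2 of 58 and 8 of 271 cells held one. Cells thinned to 1500 UMIs gave 60% and 84.5% in inhibitory neurons. With 1 library per group no test was possible. The inhibitory neurons with mCherry held 1 and 3 Homer1 UMIs, so Homer1 could not be compared in the cells that carried the reporter.

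Excitatory neuron markers were higher in CC083 in every non-neuronal class with a tested marker, the lowest class median log2 being 2.04, in astrocytes. Free RNA from neurons would reach every class of a library, but the median of 2.04 restates the observation and does not decide for that account. Doublets of a glial cell and a neuron would put most marker UMIs of microglia into few cells; the highest share in cells with more than 3 was 6.74%, against that account. Within CC083 the marker level was higher in replicate 1 than in replicate 2 in each non-neuronal class, as was the neuron share (12.2% against 4.29%). It was 301 against 109 CPM in microglia, 369 against 132 in endothelial cells and 391 against 270 in astrocytes. A gain of neuronal transcripts set by the line alone would not give this difference. These libraries also differed in batch, so free RNA and a real gain in every glial class of CC083 both stay open. The CC083 libraries held the most excitatory neurons, but knockdown replicate 2a, with 0.0139% of them, had 74.9 CPM of the markers in microglia, above 46.3 CPM in scramble replicate 1 with 2.21%.

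Of 70 genes called in 5 or more classes, 69 went in a single direction. Reads shared between paralogs need sequence in common: 16.7% (11 of 66 with sequence, CI 8.62 to 27.9) shared at least 50% of their 3' ends with another gene, above 3.50% of background genes (Fisher exact p 3.2e-05) and below what an account of most of them needs. Free RNA from neurons needs genes higher in CC083 and highest in excitatory neurons among the CC025 classes, which held for 23.2% (16 genes, CI 13.9 to 34.9), also below that. Free RNA from other classes was not tested and stays open. Prss56, which led the genes of an astrocyte cluster, was called higher in 7 classes, astrocytes among them. A strain variant against the reference could remove the reads of a gene in 1 line; 23.2% of the genes (16) lay under 5% of the other line's CPM, which leaves this open, as it does a difference in the regulation of the genes themselves.

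Mitochondrially encoded genes were higher in knockdown microglia, at a median log2 of 0.64. The call (adjusted p 2.6e-04) did not pass with an estimated correlation (0.788), which was not run with libraries left out. Scramble replicate 2a, whose cells held a median of 0.126% mitochondrial UMIs, may account for part of the difference: without it the median was 0.16 with adjusted p 0.999. The median also fell to 0.21 (adjusted p 0.0386) without knockdown replicate 2a, so that library took part as well. Low mitochondrial RNA was not confined to scramble replicate 2a: the microglial cluster with a median of 0.123% held 13441 of its cells and 4352 of knockdown replicate 1. With only cells of at least 0.5% mitochondrial UMIs kept, the median log2 was still 0.51, with 13 of 13 members above 0. Without both 2a libraries the list was lower in knockdown, at -0.27 (adjusted p 6.6e-04). A loss of mitochondrial RNA in preparing the scramble library or a difference in its mice would give the same values.

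Regrouping the 6 knockdown and scramble libraries gave 10 splits per class, too few for a share under 0.05, and the real split called 0 genes. The highest other counts were 273 in microglia, 222 in endothelial cells, 22 in border macrophages and 23 in oligodendrocyte precursors. Each came from the split with knockdown replicate 1, scramble replicate 1 and knockdown replicate 2a together against the rest. That split parted only the 2a pair, and the cause of its calls was not tested. The 4 splits that parted all 3 pairs called 0 genes in each of the 4 classes.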

How the results depend on the processing

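For knockdown against scramble the 0 calls became 28 with a replicate block, 26 with 2a and 2b summed and the block, 41 without both 2a libraries and with the block, 106 with no filter on low counts, 2 by DESeq2 and 1 with only the 2 groups, and 0 to 2 with a library left out. For CC083 against CC025 the 3327 calls became 7984 with the block, 6092 with no filter and 1610 to 4066 with a library left out, where a lone library is assumed to vary like the other groups. By class these were 1219, 1206, 190 by DESeq2 and 300 to 730 in astrocytes, 448, 207, 20 with at least 1000 UMIs, 21 with only the 2 groups and 58 to 124 in excitatory neurons, and 1621 with the block, 1529 by DESeq2 and 418 to 876 in microglia. More genes tested explains part of the count with no filter; for the others the cause was not tested. The 174 list tests that passed became 206 with the block, 167 with RLE size factors and 141 to 183 with a library left out, but 0 with an estimated correlation, 0 with the block and an estimated correlation, and 1 by fry. Among the gene and list calls within a class that are printed in the text, the block ended only that of mitochondrially encoded genes in knockdown fibroblasts (adjusted p 0.0084, with the block 0.115). It ended the call of cholesterol synthesis between microglia and astrocytes at an estimated correlation (adjusted p 0.0338, with the block 0.501). With a library left out Homer1 turned direction over all knockdown and scramble cells (range -0.548 to 0.233), in their oligodendrocytes (-0.180 to 0.276), border macrophages (-0.0262 to 1.15), microglia (-0.128 to 0.0403) and oligodendrocyte precursors (-0.0433 to 0.656), and in excitatory neurons (-0.714 to 0.0712) and oligodendrocyte precursors (-0.124 to 0.127) of the lines. It also turned in knockdown microglia with doublets kept (4.3e-04), in knockdown oligodendrocyte precursors with at least 0.5% mitochondrial UMIs (-0.0707), and in oligodendrocyte precursors of the lines with at most 10% mitochondrial UMIs (-0.0146) or doublets kept (-0.0358). Igfbp5 in knockdown oligodendrocytes ran from -2.72 to 5.98. The excitatory share in knockdown ran from -1.0 to 0.0954 points against scramble, and the correlation of the comparisons from 0.0143 to 0.266 in microglia and from -0.233 to -0.0763 in astrocytes. The cause was not tested. Among the main call counts, list counts, Homer1 values, neuron shares and correlations, 134 stayed the same or close, 38 moved and 3 turned direction. Of the other values 1822 kept direction and side of the threshold or, for counts, stayed equal or close to the main count. A further 84 counts moved, 42 values became stronger, 60 became weaker and 14 turned direction. The excitatory neurons of the knockdown and scramble libraries (1 to 271 cells) held 0 to 436 Homer1 UMIs per library, and this depth limits what could be detected in them.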

Other observations

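Immature neurons made up 4.11% of the cells of knockdown replicate 1 and 3.32% of those of scramble replicate 1 (804 and 407 cells), and 0.00532% to 0.0868% of those of the other knockdown and scramble libraries. Genes near Homer1 on chromosome 13 had a median log2 fold change of 0.36 in astrocytes of CC083 against CC025 (11 of 13 above 0, adjusted p 0.0496, with estimated correlation 0.779, 0 members called and 0 passing when adjusted over the list alone), and the call was lost without CC025 replicate 1 (0.0872) or CC083 replicate 1 (0.138). In excitatory neurons the same genes had a median of 0.21 and did not pass (adjusted p 0.20).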
